A study of Mus musculus with 6 samples.

How the data were processed

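Reduced representation bisulfite sequencing (RRBS) was carried out on genomic DNA of quadriceps muscle from C57BL/6 mice, 3 samples of exercised mice, which ran on a motor-driven treadmill during a training period of 4 weeks, and 3 of sedentary mice. In RRBS, DNA is digested with a restriction enzyme that cuts at CpG-containing sites, treated with bisulfite and sequenced, so that an unmethylated cytosine is read as T and a methylated one as C. Per the labels' protocols, DNA was taken 3 hours after the last bout of training. The submitters' processing notes name Trim Galore 0.2.5, cutadapt 1.0, Bismark 0.7.7, Bowtie 0.12.9 and the genome build mm9. The role and settings of each tool are not given in the sources used here. Nothing in the labels says that the 3 samples of a group came from separate animals, so the p-values measure the spread between these samples.

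The authors deposited 1 table for the whole series with 268725 cytosine positions in 10755 regions of 3000 bp, each keyed by a RefSeq transcript. How the regions were placed relative to their genes is not given in the sources used here. For each sample the authors deposited the methylated fraction of each position (0 to 1) and the count of reads covering it. These deposited coverage counts were at least 10 in all 6 samples at every listed position, and the fraction times the coverage came out whole within 0.00236 of a read, so methylated and unmethylated read counts were taken from their product. The 2 strands of a CpG were listed as separate, adjacent positions. The authors also deposited a difference of group means, a p-value and a class for each position. Recomputation showed that the deposited p-value equals an equal-variance test of the 6 fractions with no adjustment for multiple testing, within 5.0e-10, and that the strong classes begin at a difference of 20 percentage points. No other column of values per sample was present, and all 6 samples were used.

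Gene symbols were matched for 10655 of the 10755 transcripts through a RefSeq table made for the assembly GRCm38.p6, which was used for names only. All coordinates are those of the deposited table (mm9) and no reference genome was used.

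Total coverage was 14556783, 17815556 and 16415619 calls in exercised samples 1 to 3, and 15509309, 18656340 and 9153526 in sedentary samples 1 to 3, with median coverage per position of 46, 55, 49, 45, 59 and 27 reads. No molecular identifiers are named in the labels, so reads are not known to be independent molecules and intervals cover counting error only. For every pair of samples the mean chi-square per position was above 1, the value that sampling noise alone gives, with a lowest value of 1.64 (exercised 2 and 3), and no sample was treated as a duplicate of another.

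Differential methylation was tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) on methylated and unmethylated counts, with a term for each sample and a term for the group on the methylated counts, no dispersion trend, and Benjamini-Hochberg adjustment at 0.05. It was run on single positions, on counts summed over fixed 1000 bp windows and on counts summed over each deposited region, here called a gene region, the last 2 with at least 3 positions. Units with no methylated or no unmethylated read in all 6 samples were left out. The level of a gene region is the share of its reads that were methylated. Fixed gene lists (15) were tested on log2((methylated + 2)/(unmethylated + 2)) with camera (preset correlation of 0.01, and an estimated correlation) and fry from limma 3.58.1. Values of 1 number per sample were compared with exact two-sided permutation tests over the 10 splits of 3 against 3, for which the smallest possible p is 0.1. Calculations in Python 3 used numpy, scipy and pandas.

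Designs, gene lists, the naming rule and most alternatives were fixed before the data were examined. The naming rule took, per direction, the 10 gene regions with the largest change among those past the threshold and, where fewer passed, those with the smallest unadjusted p at a mean coverage of at least 20 reads. It added the 2 members of each list with the smallest p, the genes Ppargc1a, Pdk4, Ppard, Mef2a, Myod1 and Dnmt3a where measured, and the 5 largest differences per direction in the authors' deposited table. The last were taken among positions with an unadjusted p under 0.05, a limit the rule did not state. Genes named outside this rule are said to be so where they appear. The alternatives were a replicate block, leaving out each sample, a coverage of at least 20, removal of positions above the 99.9th percentile of coverage, removal of the sex chromosomes, other tests (limma, a quasi-binomial model, Fisher's exact test on pooled reads), a minimum difference of 10 points, merged strands, quantile normalization, 200 bp windows, at least 5 positions and a smaller offset of 0.5. They also included only positions at a mean level of 10% to 90% and, for the mean level per sample, the share of all reads methylated. Alternatives that leave out stand-alone positions or keep only methylated surroundings, thinning of reads to equal depth, and leaving out samples for similarity and the X chromosome were chosen after seeing the data. A stand-alone position has a mean level of at least 10% while the median level of the other positions within 30 bp, the adjacent base left out, is under 10%. A position of at least 10% whose neighbours' median is also at least 10% is said to have methylated surroundings.

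The models were tested on simulated data, with counts drawn at the real coverage and 50 units per size of shift. Only units at intermediate levels were shifted. At the spread seen between replicates, the test on 10021 simulated gene regions recovered 42% of those shifted by 10 points and 98% of those shifted by 20 points, and that on 13605 windows recovered 38% and 98%. The test on 253960 single positions recovered 0% even at a shift of 40 points, and 92% at 40 points when the spread was set near counting error. At the replicate spread, 74% of positions shifted by 40 points had an unadjusted p under 0.05 (edgeR). The simulation used 1 spread for all units and no structure shared between samples, so it may be more favourable than the data, which was not tested. It also called 14 unchanged gene regions and 15 unchanged windows. The shift of 40 points and the smaller spread were added to the simulation after the first results for single positions were seen. Among simulated lists of 20 regions, camera found 100% at a shift of 0.25 on the log2 odds scale and 4% at no shift. Members of the simulated lists were drawn independently. Estimated correlations within the real lists ranged from -0.285 (leukocytes) to 0.211 (fibroblasts), so these shares need not hold for the real lists.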

Results

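Methylation of single cytosines was measured by RRBS in quadriceps muscle, in 3 samples of exercised and 3 of sedentary C57BL/6 mice, to ask which sites and genes differ in DNA methylation after 4 weeks of treadmill training. The deposited table covered 268725 positions in 10755 gene-keyed regions on the 19 autosomes and the X chromosome (mm9). Total coverage ranged from 9153526 calls in sedentary sample 3 to 18656340 in sedentary sample 2. Most positions were nearly unmethylated, with 185495 (69.0%) at a mean level under 10%. Of the 83230 positions at 10% or more, 68436 (82.2%) were stand-alone positions in otherwise unmethylated surroundings.

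The mean methylation level over the deposited positions did not separate the groups. The mean level was 20.7% ± 0.324 in exercised and 20.6% ± 0.293 in sedentary samples (SD, n = 3 each), a difference of 0.181 percentage points (exact permutation p = 0.6, smallest possible 0.1). Leaving out 1 sample gave differences from -0.000306 points (without exercised sample 1) to 0.312 points (without exercised sample 3), and 0.0159 without sedentary sample 3. Without stand-alone positions, which also enter the levels of gene regions, the means were 6.31% ± 0.239 and 6.18% ± 0.281. On the X chromosome the means were 22.2% ± 0.670 and 22.0% ± 0.288 (exact permutation p = 0.8), with differences from -0.17 points without exercised sample 1 to 0.453 points without exercised sample 2. Positions under 10% averaged 2.06% ± 0.323 and 1.91% ± 0.304, and positions with methylated surroundings averaged 56.2% ± 1.08 and 56.5% ± 0.743 (exact permutation p = 0.6 and 0.8). The level was higher in exercised samples at 136500 positions and lower at 117173, so that 53.8% of the differing positions were higher (exact permutation p = 0.3). This share was 49.4% without exercised sample 2 and 47.9% at positions with methylated surroundings. Correlation of levels between samples averaged 0.963 within groups and 0.964 between groups (one-sided exact permutation p = 0.9).

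**Figure D1:**
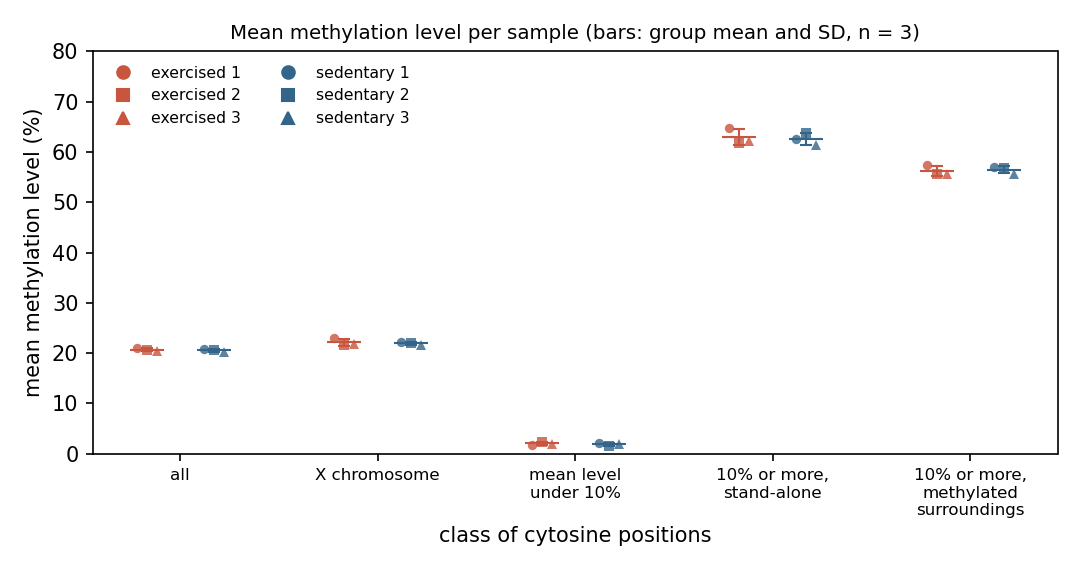
Mean methylation level (%, y axis) of each sample for classes of cytosine positions (x axis). Points are samples, horizontal lines are group means and bars are SD (n = 3). Over all positions both groups lie near 21%, at 20.7% and 20.6%, and the samples of the groups overlap in every class shown.

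No gene region passed the threshold, and those with the smallest p in each direction differed by up to about 15 percentage points. The region of Tmem88, a transmembrane inhibitor of Wnt signalling (chromosome 11, 69210737 to 69213736), was methylated at 63.5% ± 2.37 in exercised and 48.7% ± 3.44 in sedentary samples (SD, n = 3), a difference of 14.8 points over 19 positions at a mean coverage of 45.4 reads (edgeR adjusted p = 0.5). The region of Tdrd1, a Tudor-domain gene of the piRNA pathway in germ cells (chromosome 19, 56898699 to 56901698), was at 62.6% ± 3.12 in exercised and 76.7% ± 0.399 in sedentary samples, a difference of -14.0 points over 16 positions at 37.5 reads (edgeR adjusted p = 0.451). All 3 exercised samples lay above all 3 sedentary samples for Tmem88 and below them for Tdrd1. Neither region held a stand-alone position, yet the unadjusted p of both (edgeR) depended on such positions elsewhere. With them left out of all regions, it moved from 9.98e-05 to 0.0421 for Tmem88 and from 4.50e-05 to 0.0319 for Tdrd1. At adjacent pairs of positions, which are the strands of 1 CpG, Tmem88 differed by 11.3 points (SE 5.38) on the first base and 24.9 (SE 5.07) on the second, and Tdrd1 by -20.2 points (SE 7.12) on the first base and -0.719 (SE 3.74) on the second, over 5 pairs in each region.

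The other regions named with higher values in exercised samples were Entpd2, Arl4d, Nrn1, Smu1, Klc4, Hsd17b2, Nup210, Krt83 and Scaf8. Hsd17b2, a steroid dehydrogenase that oxidises oestradiol and testosterone, stood at 84.7% ± 7.13 against 70.6% ± 4.5 over 3 positions. Klc4, a kinesin light chain, stood at 96.4% ± 1.89 against 88.0% ± 3.98 over 4 positions. Krt83, a hair keratin, stood at 84.3% ± 1.09 against 73.5% ± 7.21, and its difference of 10.8 points was 6.69 without sedentary sample 1 and 19.6 at positions covered at least 20 times. Arl4d, a small GTPase of the ARF family, stood at 4.97% ± 1.40 against 0.460% ± 0.796 over 5 positions. Entpd2, an ectonucleotidase that hydrolyses extracellular ATP, stood at 24.5% ± 1.29 against 16.3% ± 3.02, a difference of 8.27 points that was 2.34 points without stand-alone positions. The difference of 6.77 points for Nup210, a nuclear pore protein, turned to -0.135 points without them. The splicing factor Smu1 differed by 6.12 points, the neuronal growth factor Nrn1 by 6.28 and Scaf8 by 3.18. Without stand-alone positions the Nrn1 difference was 3.62 and the Scaf8 difference 1.61 points.

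Among regions with lower values in exercised samples, Mark2, a microtubule affinity-regulating kinase, stood at 62.2% ± 2.79 against 74.6% ± 2.30 over 5 positions. Adad1, a testis RNA-binding protein, stood at 41.9% ± 2.92 against 53.5% ± 5.60. Sirt6, a nuclear deacetylase, stood at 43.4% ± 6.52 against 55% ± 2.88, and its difference of -11.6 points was -0.789 at positions covered at least 20 times. Slc5a5, the sodium-iodide symporter, stood at 32.6% ± 4.25 against 43.3% ± 4.5, and Fbxo46, an F-box protein, at 55.9% ± 4.52 against 68.2% ± 2.13. The Polycomb-group gene Sfmbt2 differed by -8.86 points, the mucin Muc20 by -9.16, Wfdc9 by -7.57 and Opa3, which encodes a mitochondrial protein, by -3.85. Muc20 and Wfdc9 rested on 3 positions each, and Wfdc9 lay near full methylation, at 92.0% ± 5.57 against 99.6% ± 0.770. The Opa3 difference was -1.74 points without stand-alone positions, and at positions covered at least 20 times the Adad1 difference was -4.97 and the Sfmbt2 difference -14.9 points. In these 20 regions all exercised samples lay on 1 side of all sedentary samples, and outside Tmem88 and Tdrd1 each had an edgeR adjusted p of 1.0. Over all 10021 gene regions, 727 (7.25%) had groups that did not overlap, where chance gives 10%.

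**Figure D2:**
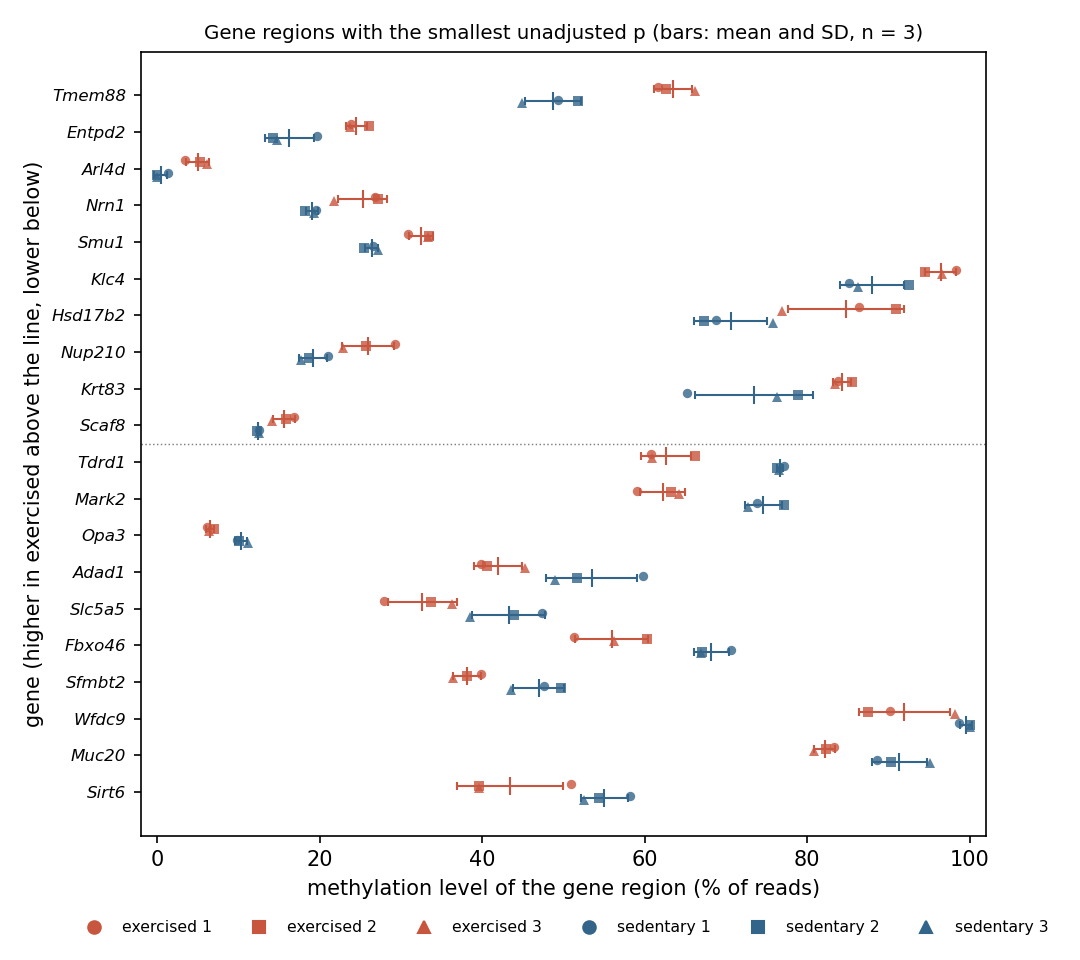
Methylation level of the gene region (% of reads, x axis) for the 10 genes with the smallest unadjusted p in each direction (y axis). Points are samples, vertical ticks are group means and bars are SD (n = 3). None passed the adjusted threshold. Tmem88 is at the top of the genes higher in exercised samples (63.5% against 48.7%) and Tdrd1 at the top of those lower (62.6% against 76.7%).

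In edgeR's quasi-likelihood test, 0 of 10021 gene regions had an adjusted p under 0.05, and 237 (146 higher, 91 lower) had an unadjusted p under 0.05. The latter count was 601 without exercised sample 3 (530 higher, 71 lower) and 404 without stand-alone positions. Without sedentary sample 2 it held 150 higher and 195 lower regions, and without exercised sample 2 it held 106 of each. The same test gave 0 of 13605 windows (381 unadjusted) and 0 of 253960 single positions (8426 unadjusted, 3.32%). Without exercised sample 3 there were 708 unadjusted windows and 4476 unadjusted positions, and without exercised sample 2 there were 4440 unadjusted positions. limma on levels and on M values and the quasi-binomial model also gave 0 at each of the 3 scales. Fisher's exact test on reads pooled over the replicates, which does not include the spread between replicates, gave 669 gene regions, 724 windows and 12354 positions.

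Over all gene regions the median difference was 0.390 points, and -0.00956 points without exercised sample 1, which is the background for the gene lists. Genes of muscle identity and contraction showed differences of both signs. Of the 19 measured regions of myogenic regulators, 13 were higher and 6 lower, with a median of 0.343 points. Mef2d, a MADS-box transcription factor of muscle differentiation, stood at 21.7% ± 6.03 against 15.5% ± 4.45, and Hdac5, a class IIa deacetylase that represses MEF2, at 13.6% ± 1.28 against 11.4% ± 1.94. The Mef2d difference of 6.23 points was 4.12 without exercised sample 2 and 9.68 without exercised sample 3. The Hdac5 difference of 2.25 points was 0.296 without stand-alone positions and 1.30 without sedentary sample 2. Mef2a stood at 21.1% ± 0.815 against 21% ± 1.34, with differences from -0.571 to 0.759 points across the alternatives. Ppargc1a and Myod1 were not among the tested regions. Of 11 sarcomere regions, 5 were higher and 6 lower. Tpm1, a tropomyosin, differed by 1.60 points and Actn2, the Z-disc alpha-actinin, by -0.934 over 4 positions, at 0.641% ± 1.11 against 1.58% ± 0.379. Their ranges across the alternatives were 0.534 to 2.20 and -1.58 to -0.614 points. None of these members passed the test over all genes or adjusted over the list alone.

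Both lists of metabolic genes had medians above that of all gene regions, as did the fibroblast, smooth muscle, DNA methylation machinery and Hox lists. Neither metabolic list passed the test. Of 25 regions of mitochondrial and oxidative genes, 16 were higher, with a median of 0.829 points. Ucp2, a mitochondrial uncoupling protein, stood at 19.5% ± 2.03 against 15.0% ± 2.19, and Acadm, the medium-chain acyl-CoA dehydrogenase, at 27.6% ± 2.64 against 23.1% ± 3.18. Without stand-alone positions the Ucp2 difference of 4.42 points was 2.41 and the Acadm difference of 4.47 points was 1.72, and the latter was 2.66 without sedentary sample 2 and 2.94 without exercised sample 2. Pdk4, a kinase that inhibits pyruvate dehydrogenase, stood at 44.1% ± 5.53 against 41.6% ± 1.96, and Ppard, a lipid-sensing nuclear receptor, at 23.2% ± 4.06 against 21.2% ± 1.45. Without exercised sample 1 the Pdk4 difference was -0.383 and the Ppard difference 0.0243 points, and without exercised sample 3 they were 5.11 and 4.08 points. Of the 5 Pdk4 positions 3 were stand-alone. Without them its difference of 2.55 points turned to -3.23, on too few positions for the test. The Ppard difference of 2.04 points was 1.53 without stand-alone positions. Of 22 regions of glucose metabolism and insulin signalling, 15 were higher, with a median of 0.887 points. Prkaa1, a catalytic subunit of AMP-activated kinase, stood at 15.3% ± 1.13 against 13.2% ± 0.0714, and Gbe1, the glycogen branching enzyme, at 23.8% ± 0.941 against 22.3% ± 0.379. Without stand-alone positions the Prkaa1 difference of 2.10 points was 1.36 and the Gbe1 difference of 1.51 points was 0.315. The adjusted camera p of both lists was 0.647 (limma).

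Of 25 regions of acute exercise and stress genes, 15 were higher and 10 lower, and their median of 0.337 and mean of -0.0170 points differed in sign. The camera direction of this list was lower (adjusted p = 0.679, limma). Gadd45g, a stress-induced gene, differed by 3.72 points and Vgf by 2.02. Without exercised sample 1 these differences were 1.08 and 0.472 points, and without stand-alone positions 1.92 and -0.125. Of 13 angiogenesis and hypoxia regions, 7 were higher, and Hif1a, the oxygen-regulated transcription factor, differed by 2.17 points and Kdr, a VEGF receptor, by 1.97. Without exercised sample 1 these were 0.659 and 0.740 points, and their ranges across the alternatives were 0.659 to 3.31 and 0.740 to 3.89 points. Among 10 regions of the DNA methylation machinery, 6 were higher. Dnmt1, the maintenance methyltransferase, stood at 33.8% ± 1.71 against 21.8% ± 6.4, and its difference of 12.1 points was 4.25 without stand-alone positions. Tet2, a 5-methylcytosine dioxygenase, stood at 12.4% ± 0.766 against 10.5% ± 1.0, and its difference of 1.96 points was 0.478 without them. The 2 Dnmt3a regions differed by -0.120 and -1.26 points, with ranges of -0.512 to 0.161 and -2.07 to -0.0830 points across the alternatives. The smallest p in this list was 0.113 when adjusted over the list alone (edgeR).

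Imprinted genes, which carry methylation on 1 parental allele, ranged widely in level. Plagl1, Zrsr1, Nap1l5, Zdbf2 and Grb10 are outside the naming rule and were chosen after their values were seen. Plagl1 stood at 53.8% ± 3.86 in exercised and 52.0% ± 9.14 in sedentary samples, Zrsr1 at 52.1% ± 6.57 and 52.7% ± 1.22, and Nap1l5 at 56.3% ± 9.61 and 56.5% ± 11.8, whereas Zdbf2 stood at 14.6% ± 1.17 and 14.1% ± 0.391 and Grb10 at 17.9% ± 0.763 and 18.6% ± 1.45. Of the 62 Zdbf2 positions 13 were stand-alone, and of the 50 Grb10 positions 14, while Plagl1, Zrsr1 and Nap1l5 held 0. Of the 21 imprinted regions, 6 were higher and 15 lower, with a median of -0.534 points. A Gnas region stood at 46.0% ± 3.76 against 58.7% ± 17.9, and its difference of -12.7 points was -3.28 without sedentary sample 3 and -21.1 without sedentary sample 1. An Igf2 region differed by 1.61 points, or 0.789 without sedentary sample 2 and 2.48 without sedentary sample 3. Of 29 Hox regions, 17 were higher and 12 lower. Hoxa5 differed by 5.52 points and Hoxa11 by -7.58.

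No list of markers of other cell types passed the test. Of 9 adipocyte regions, 6 were lower. Slc2a5, a fructose transporter, stood at 70.4% ± 3.05 against 78.9% ± 1.98, and Lep, the leptin gene, at 66.8% ± 7.10 against 74.9% ± 7.83, with Lep differences from -12.1 to -4.33 points across the alternatives. Of 8 endothelial regions, 5 were lower, among them Egfl7 by -5.50 points and Sox17 by -4.17. The Sox17 difference ranged from -6.58 without sedentary sample 2 to 0.338 without sedentary sample 1, and the Egfl7 difference from -9.63 without sedentary sample 3 to -2.93 without exercised sample 3. The 3 leukocyte regions included Coro1a at -2.54 points and Ikzf1 at 0.421. The Coro1a difference ranged from -4.50 without exercised sample 2 to -0.456 without exercised sample 1, and the Ikzf1 difference from -0.422 without sedentary sample 2 to 1.31 without sedentary sample 3. Of 7 fibroblast regions, 6 were higher, with Fbn1 at 2.01 and Tbx15 at 2.20 points. The Fbn1 difference ranged from -0.220 without sedentary sample 2 to 3.50 without exercised sample 3, and the Tbx15 difference ranged from 0.268 at positions covered at least 20 times to 4.26 without exercised sample 3. The 8 nerve and Schwann cell regions included Sox10 at 8.17 and Nefm at -2.66 points, and the 7 smooth muscle and pericyte regions included Lmod1 at -7.96 and Smtn at 1.66 points. Sox10 ranged from 1.05 points at positions covered at least 20 times to 13.5 without exercised sample 2, and Nefm was at -1.73 without exercised sample 3. Lmod1 ranged from -13.0 to -4.81 points across the alternatives, and Smtn from -0.270 without stand-alone positions to 2.85 at positions covered at least 20 times. Of the 15 lists, 0 passed camera after adjustment (smallest adjusted p = 0.374, shared by the imprinted, endothelial and adipocyte lists, limma), and the smallest adjusted p with an estimated correlation was 0.935. fry, which tests a list by itself, likewise gave 0 lists, for members that move on balance in 1 direction and for changes in either direction. The medians of the acute exercise, angiogenesis, Hox, nerve and smooth muscle lists were above 0 while camera, which sets a list against all other regions, gave the lower direction, and the smooth muscle mean was -0.543 points. No member of any list passed over all genes or adjusted over the list alone, and unadjusted counts were at most 2 members per list.

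In the authors' deposited table, 7961 positions had an unadjusted p under 0.05, or 3.13% of the 253960 tested. Uniformly spread p-values would give 12698 at that threshold. The same test on the other splits of the 6 samples called 6544 to 9727 positions, a range that holds the real count. Of the 7961 positions, 5464 were higher and 2497 lower in exercised samples. Benjamini-Hochberg adjustment of the deposited p-values over all tested positions left 57 under 0.05, with a smallest value of 5.75e-59. At all 57 the 3 levels of 1 group were equal, so that this group had no spread, and the largest difference among them was 14.1 points. The excess of higher positions lay at levels under 10%, with 4379 higher and 1278 lower. At 10% or more there were 1085 higher and 1219 lower. Differences of 20 points or more were listed at 223 higher and 314 lower positions, of which 389 (72.4%) were stand-alone positions. Among all positions at a mean level of 10% or more the stand-alone share was higher, at 82.2%. For the 371 positions with a difference of 20 points or more and a measured adjacent base, the adjacent base differed in the direction of the call at 40.4%, or 49.3% for higher and 34.5% for lower positions. Adjacent bases with no difference between groups, as at Elf1 and Atmin, count as not in that direction. These shares by themselves therefore do not show an opposite change on the adjacent base. On average the adjacent base differed by 0.666 points (SE 0.760) at higher and by 1.55 points (SE 0.438) at lower positions. The called positions themselves averaged 26.3 and -26.3 points, so on average the adjacent base did not share the called difference. Other positions 2 to 30 bp away differed on average by 1.66 points (SE 0.330) beside higher and by -0.859 points (SE 0.234) beside lower positions. These SEs are taken over positions of the same 6 samples and do not measure the spread between samples. The called positions were also chosen by their difference in these data, so the values beside them are not a test of the groups.

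Among positions with an unadjusted p under 0.05 in the authors' deposited table, the largest positive difference was 51.1 points at 2700081O15Rik (chromosome 19, 7491338), followed by 49.4 points at Hic2, 49.2 at Znrf4, 46.4 at Elf1 and 44.4 at Tmem88 (chromosome 11, 69212586). At that Tmem88 position the levels were 93.8, 64.0 and 78.1% in exercised and 39.3, 32.0 and 31.3% in sedentary samples, at a coverage of 16, 50, 32, 28, 25 and 16 reads. The adjacent base differed by 23.3 points. The most negative differences among these positions of the authors' deposited table were -54.3 points at Atmin (chromosome 8, 119467229), -47.1 at Msantd2, -45.5 at Ube2e3, -45.0 at Kcng3 and -43.9 at Ccndbp1. At the Atmin position the neighbouring positions had a median level of 1.56%, and the adjacent base was at 100% with a difference of 0 points.

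**Figure D3:**
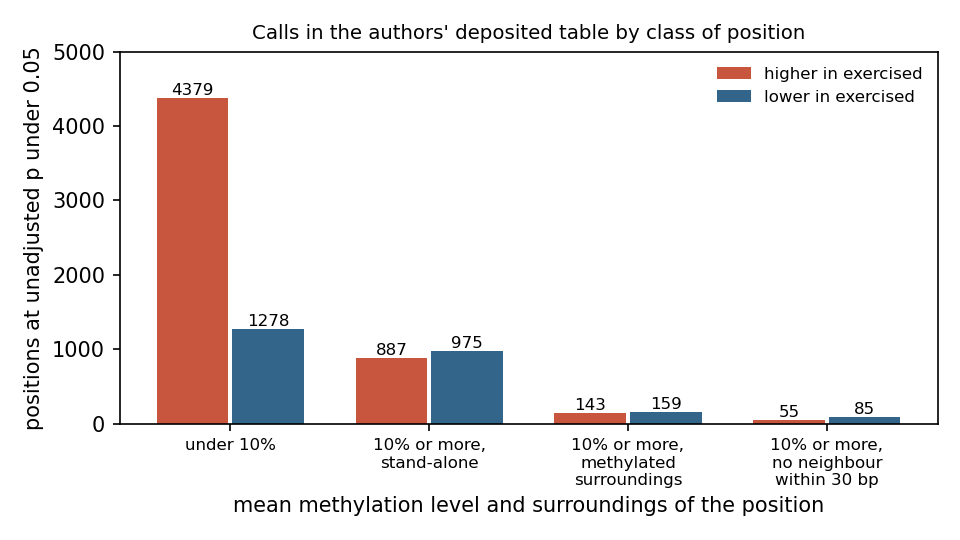
Number of positions with an unadjusted p under 0.05 in the authors' deposited table (y axis) by the mean level and surroundings of the position (x axis). Bars show positions higher and lower in exercised samples. Higher positions outnumber lower ones under 10% (4379 against 1278) and do not in the classes of 10% or more.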

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

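Alternatives without stand-alone positions, those on positions with methylated surroundings, the thinning of reads and the leave-one-out values for similarity and the X chromosome were chosen after seeing the data. The counts of 0 positions, 0 windows and 0 gene regions held under every alternative run except 2. Fisher's exact test on pooled reads gave 12354 positions (6054 higher, 6300 lower), 724 windows (524, 200) and 669 gene regions (504, 165); by its construction it leaves out the spread between replicates. Merging both strands of a CpG gave 1 position, in the Grb10 region (chromosome 11, 11936714), named here after its values were seen: levels were 0% in all exercised samples and 11.5, 9.33 and 8.26% in sedentary samples (edgeR adjusted p = 0.00615); the cause was not tested. Its separate bases were at 16.2, 16.9 and 0%, and 5.93, 4.40 and 12% in sedentary samples. Leaving out each sample in turn gave 0 to 0 calls at all 3 scales and 0 to 0 lists with camera. With fry for changes in either direction it gave 0 to 1 lists, the 1 without exercised replicate 3 or sedentary replicate 2; the cause was not tested. The overall difference ranged from -0.000306 (without exercised replicate 1) to 0.312 points, that of the X chromosome from -0.17 to 0.453 points, the correlation within minus between groups from -0.00603 to 0.00197, and the share of higher positions from 49.4% (without exercised replicate 2) to 57.2%. With methylated surroundings that share was 47.9%. With the replicate number as a replicate block there were 0 calls at all 3 scales and 0 lists, and unadjusted counts of 1852 positions, 337 windows and 204 gene regions. Same-numbered samples correlated in their deviations from the group means at 0.0222, -0.219 and -0.0393, and differently numbered samples at -0.0869 to 0.162. These few values show no sign that the numbers pair the samples but cannot exclude it. Of 55 named regions, 46 kept their sign under every alternative run and 9 did not (Mef2a, Vgf, Dnmt3a, Fbn1, Ikzf1, Sox17, Pdk4, Smtn, Nup210), 0 passed with any test other than Fisher's and 31 passed with Fisher's. The replicate block and the other tests used the same difference, so only a change of samples or positions could alter a sign. Leaving out 1 sample cannot alter it where the groups do not overlap, as in the regions named for the smallest p. The count of kept signs is therefore not a measure of robustness. With reads thinned to equal depth the deposited kind of test gave 5647 calls, against 7961. A coverage of at least 5 was not run, since the lowest coverage listed was 10. For single positions at intermediate levels, 0% of simulated shifts of 40 points were recovered at the spread between replicates and 92% near counting error, at the same coverage. At the spread between replicates 74% of these shifts had an unadjusted p under 0.05 (edgeR). Both this spread and the adjustment over all positions thus limit the test. Positions at low levels were not shifted, so the simulation does not show what the test recovers there. Other depths were not simulated.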

Other observations

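The tests on strands, fragment ends, thinning and library background, and the counts of splits for positions, windows, gene regions and the deposited calls, were chosen after their results were seen. The tests of the germline list, prompted by Tdrd1 and Adad1, and of the gene lists under other splits were chosen before their own results were seen.

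Germline genes are silenced by promoter methylation in somatic tissue, and Tdrd1 and Adad1 were among the regions with the smallest p for lower values. A list of other germline genes was written after these were seen and before it was tested, with 18 of 43 measured at a median level of 69.0%. Mael, Syce1 and Ddx4 are named after their values were seen. Mael, of the piRNA pathway, stood at 91.1% ± 3.73 in exercised and 96.0% ± 1.31 in sedentary samples, Syce1, of the synaptonemal complex, at 87.1% ± 1.60 and 92.7% ± 3.56, and Ddx4, a germ cell RNA helicase, at 72.1% ± 2.15 and 67.4% ± 6.27. Of the 18 regions 12 were lower, with a median of -0.698 points (bootstrap SE 0.823). The hypothesis that germline genes may share a shift to lower methylation was left open: camera gave p = 0.00574 with the preset correlation, which met the criterion written beforehand (under 0.05). With an estimated correlation, a requirement added afterwards, p was 0.0874, and fry gave p = 0.230. Of random lists matched on level, 3.17% were as low. With 10 splits no share under 0.05 can be reached; 3 of 10 splits gave a camera p as small, and the smallest of the other splits was 0.00456.

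High methylation was mostly on 1 strand of a CpG. Of 17721 adjacent pairs with a member at 90% or more, 15631 (88.2%) had the other member under 35%, and 104 had both at 90% or more. A candidate explanation is calls at the ends of short fragments: within 60 bp, 90.1% of neighbouring pairs of this kind followed the order low-high then high-low, at a median distance of 34 bp, and positions between them had a median level of 1.87%. Methylation of 1 strand independent of fragment ends is argued against by the 0.685% of neighbouring pairs that had the same order. An effect of exercise on the low member (exact permutation p = 0.8) cannot be told apart from none with 3 samples per group. No genome was used to locate restriction sites, so the fragment ends themselves stay untested. Stand-alone positions enter the mean level over all positions and the levels of gene regions. Whether they are calls at fragment ends was not tested. Whether calls on 1 strand account for the Tmem88 or Tdrd1 difference was left open, as the base with the smaller difference gave 11.3 points (SE 5.38) and -0.719 points (SE 3.74) over 5 pairs each, neither clear of the bound of 5 points by 2 SE, a margin added after these values were seen.

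The excess of higher calls in the authors' deposited table (68.6% of calls) was set against depth, library background and grouping. After thinning to equal depth 62.2% of calls were still higher (3510 higher, 2137 lower), so an excess remained in these samples at equal depth. At levels under 10% the share of higher calls was 70.1% after thinning and 77.4% before. Lower depth of sedentary sample 3 as a part of the cause thus stays open. No other split was thinned, so the remaining excess has no spread to be set against. Background calls that differ between libraries cannot be told apart from a group effect: levels at positions under 10% ranged by 0.629 points within a group, more than the 0.157 points between groups, and no unmethylated control was analysed here. With 10 splits no share under 0.05 can be reached; 3 of 10 splits gave a share as one-sided, with 71.6% the highest of the others. A response to training stays open and untested.

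For the tests across the genome, 10 splits of the 6 samples cannot give a share under 0.05. The real split gave 0 positions, windows, gene regions and lists, so that 10 of 10 splits gave as many whatever the others held, and this count carries no information. The highest other splits gave 3 positions, 0 windows, 0 gene regions and 0 lists. At an unadjusted p under 0.05 the real split gave 237 gene regions, 381 windows and 8426 positions, and the other splits gave 167 to 1405, 286 to 1489 and 7201 to 9984. The number of splits with at least as many as the real one, itself included, was 8, 8 and 5 of 10.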
